A study of Mus musculus with 96 samples.

How the data were processed

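Read counts were deposited for 96 wells of one plate, each well holding 1 sorted cell from fetal liver of C57/Bl6J mice at embryonic day 14.5, per the labels. Cells had been depleted of lineage-positive cells and sorted into 4 gates by Kit, CD71 and CD24, and libraries were made by Smart-seq2, per the labels' protocols. The authors aligned reads with STAR 2.4 to GRCm38 and counted them per gene with featureCounts, per the submitters' processing notes, and the deposited values are whole-number counts per gene without normalisation. The version of featureCounts, the annotation release, the strand setting and the treatment of reads shared between genes are not given in the sources used here. The header line of the table holds an empty cell more than its data lines, so its names stand shifted against the columns, and each name was taken for the column at the same place in order.

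The table held 49466 genes, of which 20754 had a read in any well, and 0 columns without a sample. Rows that name no gene held 0% of reads. Of the gene identifiers, 49326 (99.7%) are in GENCODE release M21 of GRCm38, from which coordinates are given, 1-based. For 77 symbols with more than 1 identifier, the one with most reads was used. No 2 columns were identical. A cell was kept with 50000 or more reads and 1000 or more genes, which left out 5 wells of 10596 to 16644 reads. Doublets were not called computationally, since each well was sorted as 1 cell.

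Cells are not replicates, and the labels name no animal, so counts were summed over the kept cells of each gate and no test, standard error or count of changed genes was made. Values are CPM of the summed counts with an exact Poisson interval, and ratios with an exact conditional binomial (Clopper-Pearson) interval at 95%, all covering counting error only. A count of 0 stood at a floor of 3 counts over the gate, in the alternatives too, and no ratio was given where both gates were at or below it. For the positions of the intermediates, counts of 1 and 2 stood at that floor too. Summed reads per gate set this floor at 0.0786, 0.0966, 0.0824 and 0.0846 CPM from BFUE to CFUE. Shares of cells have exact binomial intervals.

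Before the data were examined, 18 gene lists and 8 lists of cell type markers were fixed, with the rule for named genes. A list member was measured at 10 CPM or more in either gate, counted as higher or lower at 1.5-fold or more, and the list's median was set among 10000 random lists matched in size and in 20 bins of expression. Named genes had 50 CPM or more in the higher gate, a read in 50% or more of its cells, no cell with more than 50% of the reads, a 2-fold or larger difference also in the mean of per-cell CPM, and the same direction in plate rows A to D and in rows E to H. Predicted genes and pseudogenes were left out, and some genes that meet the rule are not reported here. The 12 largest and 12 smallest ratios were named for the ends and 10 of each for neighbouring gates, with the sorted markers and up to 4 members per list. These markers and members were not held to the rule for named genes, and members needed only to be measured at 10 CPM or more. Other genes named in the text were singled out after their values were seen.

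For scores, assignment and thinned shares, every cell was thinned to 500000 reads, the largest depth of those set beforehand that at least 20 cells of every gate reached. All 91 kept cells reached it. Scores are means of log2 of CPM plus 10. Alternatives were the mean of per-cell CPM, TMM factors (edgeR 4.0.16) and size factors (DESeq2 1.42.0), in R 4.3.3, other cell filters, globin, mitochondrial and ribosomal RNA genes left out of totals, plate rows A to D or E to H alone, thinned counts, the deepest cells left out, other filters for list members, other pseudocounts and other gene sets. Leaving out the BFUE cells with 100 CPM or more of Cd34, the CFUE cell of well D10, the cell with most reads of a gene, or Kit from the list of BFU-E self-renewal, was chosen after seeing the data.

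The ratio script was tested on simulated data for CFUE against BFUE with 8329 genes, of which 200 were changed. Of the 67 genes simulated at 2-fold, 95.5% lay within their interval, and of the 67 at 1.5-fold 89.6%. Counts were drawn as Poisson sums per gate, as the interval assumes, without differences between cells. This checks the script only, and not how well the intervals hold for these data. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.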

Results

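The data were single-cell RNA-seq read counts (Smart-seq2, full-length cDNA from single cells) of erythroid progenitors sorted from fetal livers of C57/Bl6J mice at embryonic day 14.5. Lineage-positive cells had been depleted before sorting with antibodies to Kit, CD71 and CD24. One 96-well plate held 4 sort gates of 24 wells each. The first gate was BFUE, for burst-forming units, and the last CFUE, for colony-forming units, the earlier and later committed progenitors of red cells. Between them lay 2 intermediate gates, named for 25 to 35% and 50 to 60% of CD71/CD24 expression and called the lower and the upper intermediate gate here. Each gate filled 3 plate columns, so plate column and gate cannot be told apart. The labels name no animal or pool, so each gate counts as 1 sample and no difference between gates has a replicate check. The 91 cells kept (23 BFUE, 21 of the lower intermediate gate, 24 of the upper one and 23 CFUE) held between 947458 and 3785903 reads in genes, with a median of 9363 genes per cell. Summed reads per gate were 38184231, 31059327, 36422769 and 35454299 in that order. Intervals below are exact 95% intervals of counting error only, and since the reads carry no molecular identifiers they are not independent molecules.

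The 3 genes whose proteins were stained for sorting checked the gates and are no findings between them. Kit (chromosome 5, 75574916 to 75656722, GRCm38), the stem cell factor receptor, was at 762, 694, 402 and 269 CPM (the summed read count of a gene scaled to a common total per gate) from BFUE through to CFUE. Tfrc (chromosome 16, 32608920 to 32632794), which encodes CD71, the transferrin receptor, was at 154, 547, 674 and 830 CPM. Cd24a was at 126, 401, 737 and 1168 CPM, and 9.26-fold higher in CFUE than in BFUE (interval 8.99 to 9.54).

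The first comparison asks how the ends of the progenitor series differ. In CFUE, genes of heme synthesis, globin and the red cell membrane were higher than in BFUE, and genes of stem and multipotent cells were lower. Hba-a1, an alpha globin gene (chromosome 11, 32283511 to 32284465), was at 934 CPM in CFUE against 7.20 in BFUE, 130-fold higher (interval 115 to 147). Slc4a1, the band 3 anion exchanger (chromosome 11, 102348824 to 102366203), was 704-fold higher, with a wide interval of 371 to 1541 since BFUE held only 9 reads. Of 16 measured heme synthesis genes, 13 were at least 1.5-fold higher and 1 lower, with a median log2 ratio of 1.68 (1.28 in plate rows A to D and 2.04 in rows E to H).

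Among heme synthesis genes, Uros was 7.82-fold higher (interval 7.36 to 8.32) and Abcb10, a mitochondrial transporter, 7.38-fold higher. Alas2, the erythroid form of the first enzyme, stood at 3 reads in BFUE and 1088 in CFUE, a ratio of 391 with an interval of 133 to 1897. Alas1, the form of that enzyme found in all tissues, went the other way and was 2.30-fold lower. Of 23 measured membrane and surface genes, 20 were higher and 1 lower, at a median log2 ratio of 2.79. They included Trim10 (465-fold, interval 252 to 970), Epb42 (21.3-fold) and Cldn13 (19.7-fold). The 1 lower member was Car1, carbonic anhydrase 1, at 420 CPM in BFUE and 5.83-fold lower in CFUE. The BFUE cell of well C3 held 42.6% of its reads there, and without that cell it was 3.49-fold lower. All 5 measured globin and chaperone genes were higher. Hba-a1 and Hba-a2 are near-identical copies, as are Hbb-bs and Hbb-bt, so the split of reads within each pair is uncertain. The medians of the heme synthesis, membrane and globin lists each lay at percentile 100 among 10000 random lists of matched size and expression. Of 14 late erythroblast markers, 13 were higher, at a median log2 ratio of 2.95.

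Stem and multipotent progenitor genes were lower in CFUE for 20 of 21 measured members and higher for 0, at a median log2 ratio of -7.25. In rows A to D alone it was -6.65 and in rows E to H -6.25. Cd34 (chromosome 1, 194938819 to 194961279), a surface protein of early progenitors, was at 441 CPM in BFUE and 0.451 in CFUE, 978-fold lower (interval 602 to 1711). Markers of other cell types moved with this list. All 6 measured neutrophil and monocyte markers were lower in CFUE, at a median log2 ratio of -8.40, and so were all 5 lymphoid markers at -8.64. The lymphoid median is the ratio of Il7r, with 0 reads in CFUE against 1289 in BFUE. It is thus a bound set by the floor of 3 counts. The myeloid enzyme gene Mpo was 437-fold lower (interval 340 to 571).

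The reads of Cd34 sat in part of the BFUE cells. It lay between 1036 and 2202 CPM in 8 of the 23 BFUE cells, which is 34.8% (exact interval 16.4 to 57.3%), and at no more than 5.16 CPM in each of the other 83 kept cells. The 8 cells held Mpo at 145 to 6209 CPM, Gata1 at 2.17 to 66.9 CPM and Klf1 at 1.92 to 71.5 CPM. The other 15 BFUE cells held Gata1, the central erythroid transcription factor, at 189 to 583 CPM and Klf1 at 167 to 1094 CPM. None of the 68 kept cells of the other gates reached 100 CPM of Cd34, which is 0% with an exact upper bound of 5.28%. Without the 8 cells, a setting chosen after the data were seen, the stem list had 18 lower members of 19 with a ratio, at a median of -3.52, and the neutrophil and monocyte median was -3.88 with all 4 members that had a ratio lower. The lymphoid median hardly moved, at -8.14, but over only 3 members with a ratio, 2 lower and 1 higher. Cd34 itself was then 3.47-fold lower, but the 8 cells had been chosen by it. Among the other kept cells 0 held 10 or more reads of it, so this ratio rests on trace reads. The heme synthesis median was 1.31 and the membrane median 2.27. Here and below, list members in this setting were those measured with all kept cells, and the cut at 10 CPM was not applied again. Members that owed their reads to the 8 cells may thus rest on trace reads. Flt3, of the stem list, reached at most 3.72 CPM in the other 15 BFUE cells, and 0 of them held 10 or more reads of it.

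**Figure D1:**
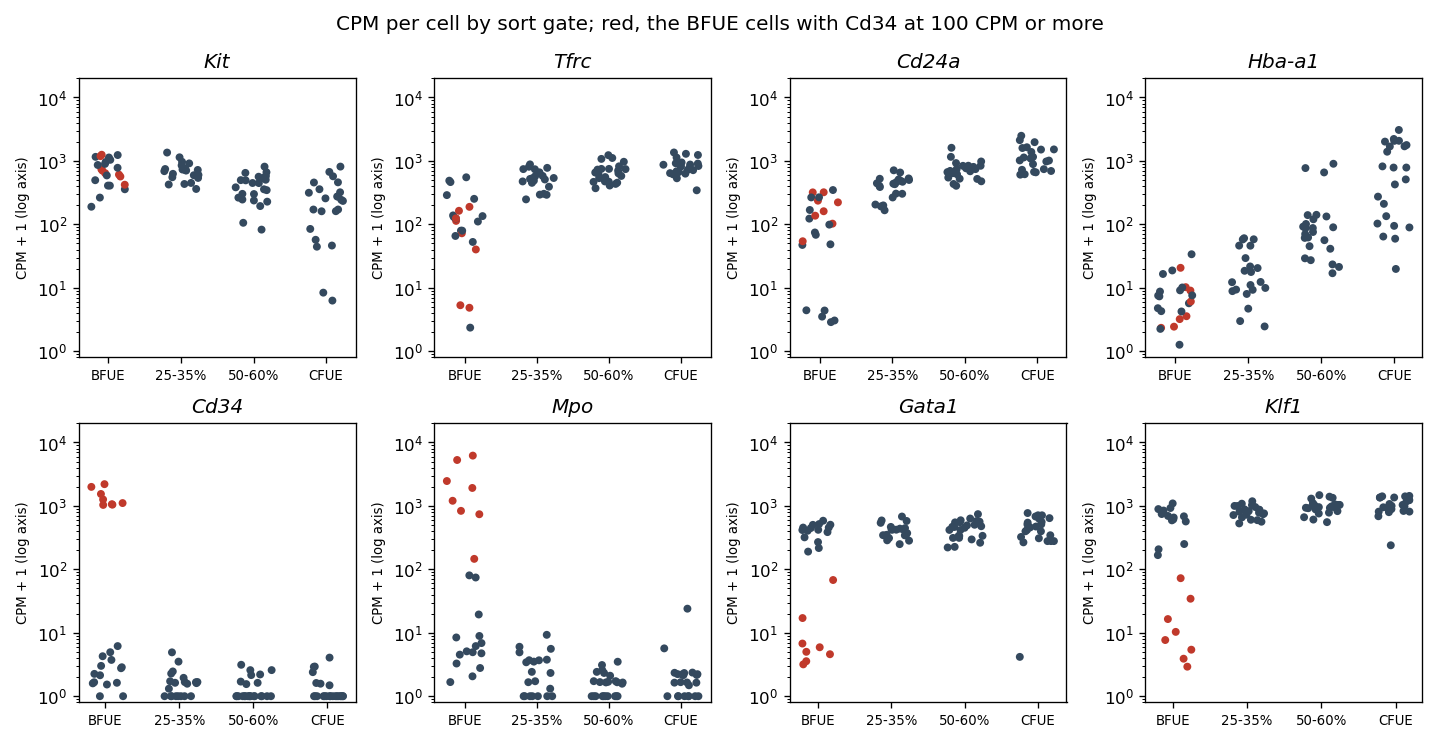
CPM plus 1 per cell on a log axis for 8 genes in the 4 sort gates, 1 point per kept cell. Red points are the 8 BFUE cells with Cd34 at 100 CPM or more, which lie above every other cell for Cd34 and Mpo, and below every other BFUE cell for Gata1 and Klf1.

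Among the 12 largest ratios in each direction, the higher genes were Slc4a1, Trim10, Hba-a1, Hba-a2, Hbb-bs, Mgll (41.9-fold), Slc46a3, Tspan15, Scd1, Rgcc (22.3-fold), Epb42 and Acp5 (19.8-fold). The lower genes included Gimap1, Mycn, Cd53, Plcb2, Lcp2, Ighm, Lsp1, Plekha2, Plac8 and Cd34. Several of the lower genes had 1 or 2 reads in CFUE, so their ratios are known only within wide intervals, such as 604 to 133090 for Gimap1. Of the BFUE reads of Lsp1 and Cd34, 99.8% came from the 8 Cd34-high cells. Gimap1, Mycn, Cd53, Plcb2, Ighm and Plac8, with these 2, are among 77 genes abundant in those cells. The cuts were 100 CPM or more over the 8 cells and at most 20 CPM in each kept cell of the later gates. They were set after the data were seen. The ratios of these genes need not hold for the other BFUE cells. A read in 50% of cells can be met by cells with fewer than 10 reads, as for Cd34. Without the Cd34-high cells Ighm, an immunoglobulin heavy chain gene, was 6.09-fold lower in CFUE.

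Transcription factors of the erythroid program were mixed. Of 20 measured, 10 were higher and 3 lower, with a median log2 ratio of 0.55 (0.25 in rows A to D and 0.70 in rows E to H). Without the Cd34-high cells 8 were higher and 3 lower, at 0.25. Hemgn was 8.48-fold higher, Sox6 5.43-fold and Mllt3 4.11-fold, while Myb was 5.44-fold lower (interval 5.04 to 5.86). Klf1 was 2.31-fold higher, and 1.60-fold without the Cd34-high cells. Of 24 measured genes of G2 and M phase, 12 were higher and 0 lower, with a median log2 ratio of 0.64 (0.29 in rows A to D and 0.91 in rows E to H), and Aurka was 2.48-fold higher. Without the Cd34-high cells 7 of them were higher, at 0.48. Of 23 S phase genes, 9 were higher and 0 lower at a median of 0.49, with Ccne1 4.12-fold and Rrm2 3.70-fold higher. Relative to this, the median of all 8701 measured genes was -0.14, and TMM scaling (edgeR) brought it to -0.03.

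Of 18 receptor genes, 14 were lower and 0 higher at a median log2 ratio of -1.94 (-1.29 without the Cd34-high cells), and Csf2rb, a cytokine receptor subunit, stood at 26.9 CPM in BFUE against 1 read in CFUE, a ratio of 955 with an interval of 171 to 37774, and of 627 without the BFUE cell of well E2, which had the highest count of it. Of 8 genes of the glucocorticoid receptor and BFU-E self-renewal list, 5 were lower and 2 higher, at -1.10. Kit, stained for sorting, is among the 5, and without it 4 of 7 were lower, at -0.70. The lower ones included Gata2 (483-fold), Tsc22d3 (7.58-fold) and Zfp36l2 (3.96-fold). Of 17 glycolysis genes, 6 were lower and 2 higher, at -0.41. Pklr, the red cell and liver pyruvate kinase, was 4.76-fold higher and Pkm, the form of other tissues, stood at 932 CPM in BFUE against 233 in CFUE. Of 9 immediate early and heat shock genes, 5 were lower at -2.00 (-0.94 without the Cd34-high cells), and the heat shock genes Hspa8, Hsp90aa1 and Dnajb1 were not among them. That median turned to 0.28 over the 4 members at 50 CPM or more. It also turned, to 0.029, over 9 members with a read in both gates, where Jund was counted in place of Egr1, so its sign hung on which members were counted.

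The median log2 ratio of iron handling genes was 0.40 with 6 of 15 higher (0.34 in rows A to D and 0.80 in rows E to H). Without the Cd34-high cells it was at 0.18, and its percentile among random lists fell from 99.5 to 91.6. The median of oxidative phosphorylation was 0.25 with 4 of 24 higher. Ribosomal proteins were at 0.14 with 0 of 24 beyond 1.5-fold, G1 cyclins and CDK inhibitors at -0.05 with 3 of 10 higher and 4 lower (-0.86 in rows A to D and 0.07 in rows E to H), and ribosome biogenesis at -0.15 (-0.34 without the Cd34-high cells). In that list Myc was 2.16-fold lower. Erythropoietin and STAT5 signalling had no clear direction, at -0.26 and percentile 30.8 among random lists, but 0.08 in rows A to D, and 5 higher and 4 lower of 13 without the Cd34-high cells. In it Epor, the erythropoietin receptor, was 3.13-fold higher and Ptpn6 6.73-fold lower. The Cd34-high cells held Epor at no more than 4.94 CPM, against 16.2 to 365 CPM in the other 15 BFUE cells. They thus lowered the BFUE value of Epor, and its ratio is not that of the other BFUE cells.

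Of the other marker lists, megakaryocyte genes were at a median log2 ratio of -3.41 over 7 members (percentile 1.35 among random lists), mast cell and basophil genes at -2.46 over 3 (percentile 8.52), hepatoblast genes at -0.94 with 8 of 9 lower (percentile 40.1), and endothelial and stromal genes at -8.49 over 2. In the last list Pdgfrb had 0 reads in CFUE, so its ratio is a bound set by the floor. Without the Cd34-high cells the 4 medians were -3.94, -0.92 (over 2 members with a ratio), -0.85 and -4.21. The only measured macrophage marker, the iron exporter gene Slc40a1, was 3.89-fold higher.

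**Figure D2:**
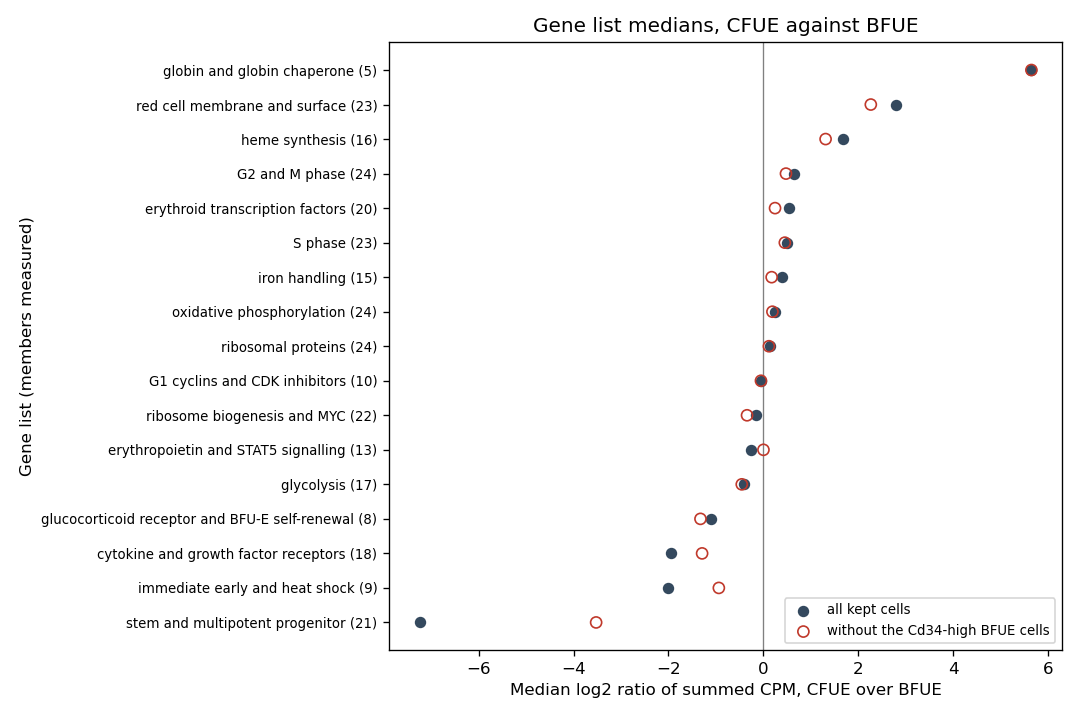
Median log2 ratio of summed CPM in CFUE over BFUE for 17 gene lists, with the number of measured members in brackets. Filled points use all kept cells and open red points leave out the 8 Cd34-high BFUE cells. The stem and multipotent progenitor list lies at -7.25 and -3.52.

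The next comparison asks what separates BFUE from the lower intermediate gate. Stem and multipotent genes were already lower there for 20 of 21 measured members and higher for 0, at a median log2 ratio of -3.64, and heme synthesis genes were higher for 7 of 14 and lower for 0, at 0.69. Sphk1, a sphingosine kinase, was 9.69-fold higher (interval 9.08 to 10.4) and Tgm2, a transglutaminase, 6.24-fold higher. Gata2, a transcription factor of early progenitors, was 12.2-fold lower (interval 11.1 to 13.4). All 6 neutrophil and monocyte markers were lower, at -7.29, and all 5 lymphoid markers at -8.15. Without the Cd34-high cells these medians were -2.89 (4 lower and 1 higher of 5 with a ratio) and -3.56 (2 lower of 3).

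Among the 10 largest ratios in each direction, the higher genes also included Tmem56, Slc30a10, Hspbap1, Atp7b, Rgcc, Taf4b, Crip2 and Lmna. The lower ones included Gem, Pear1, Slc25a45, Lcp2, Adgrl4, Emb, Ighm, Tespa1 and Plcb2. Of these, Gem, Pear1, Adgrl4, Emb, Ighm, Tespa1 and Plcb2 are among the 77 genes abundant in the Cd34-high cells. Of the BFUE reads of Adgrl4, 99.8% came from the Cd34-high cells, and without these cells it was 2.07-fold lower. Without them the stem list median was -1.50 and the heme synthesis median 0.31, and Sphk1 was 6.79-fold higher. Of 21 membrane genes, 14 were higher and 3 lower, at a median of 0.90 (1.27 in rows A to D and 0.71 in rows E to H). Rhd was 4.01-fold higher. Without the Cd34-high cells 9 membrane genes were higher, at a median of 0.53. Car1 was 9.99-fold lower, and 5.98-fold without the BFUE cell of well C3.

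The third comparison asks what separates the 2 intermediate gates. Heme synthesis genes were higher for 7 of 15 measured members and lower for 0, at a median log2 ratio of 0.52 (0.45 in rows A to D and 0.53 in rows E to H). Membrane genes were higher for 13 of 22 and lower for 0, at 0.67. Hba-a1 was 7.40-fold higher (interval 6.83 to 8.02) and Epb42, a protein of the red cell skeleton, 6.46-fold higher. Of 8 measured stem and multipotent genes, 3 were lower at a median of -0.30 (-0.19 in rows A to D and -0.41 in rows E to H), and Gata2 was 10.5-fold lower (interval 7.94 to 14.2). That median was -0.61 with no filter on low genes and -0.10 over the 4 members at 50 CPM or more. Other higher genes among the 10 largest included Scd1, Acp5, Redrum, Tprgl, Cldn13, Sptb and Rab3il1. The 10 lower genes were Cmtm7 (5.02-fold), Apoe (3.92-fold), Rgs19, Clstn1, S100a10, Arhgdib, Flna, Anxa6, Ptprcap and Cyba.

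The last step asks what separates the upper intermediate gate from CFUE. Genes of G2 and M phase were higher in CFUE for 13 of 24 measured members and lower for 0, at a median log2 ratio of 0.63 (0.37 in rows A to D and 0.77 in rows E to H), while S phase genes lay at -0.02. Slc4a1 was 61.7-fold higher (interval 50.5 to 76.1) and Hbb-bs, a beta globin gene, 11.4-fold higher. Heme synthesis genes were higher for 5 of 16 and lower for 0, at 0.51, but at 0.20 in rows A to D and 0.68 in rows E to H. Of 7 measured stem and multipotent genes, 2 were lower, at -0.44 (-0.53 in rows A to D and -0.17 in rows E to H). Further higher genes were Hbb-bt, Hba-a1, Hba-a2, Cdc25b (4.27-fold), a phosphatase of mitotic entry, Btg2 (4.26-fold), Gpr146, Trim10 and Mgll. The lower genes were Itga5 (4.05-fold, interval 3.68 to 4.47), Pdxk, Arhgdib, Erlin1, G6pc3, Sh2b3, Pisd, Ttc3, Nrros and Coq2.

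Genes that differed between the ends were used to place the intermediates, chosen in plate rows A to D and measured in rows E to H, and the reverse. For genes higher in CFUE, the lower intermediate gate stood at 51.1% of the log2 distance from BFUE to CFUE (53.2 and 49.1% in the 2 directions) and the upper one at 83.4 and 86.6%. For genes lower in CFUE, the gates stood at 59.9% and 80.4%. Without the Cd34-high cells the lower intermediate gate stood at 43.3% and 46.1%.

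Cells could be assigned back to their gates in part. With centroids from the plate rows that did not hold the cell (A to D or E to H) and 500 genes, 70 of 91 cells (76.9%, exact interval 66.9 to 85.1%) went to their own gate and all 91 to their own or the next one. In BFUE 16 of 23 cells returned, with the other 7 placed in the lower intermediate gate. In the lower intermediate gate 19 of 21 cells returned, and in CFUE 16 of 23, with the other 7 placed in the upper intermediate gate. Without the Cd34-high cells 65 of 83 cells returned, and in BFUE 12 of 15, with the other 3 placed in the lower intermediate gate. The per-cell erythroid minus progenitor score, on log2 values at 500000 reads per cell, had medians of 0.87, 2.16, 2.92 and 3.44 from BFUE to CFUE. Its SD between cells was 1.53, 0.29, 0.41 and 0.62, and 0.67 in BFUE without the Cd34-high cells. Of 21 cells of the lower intermediate gate, 15 lay within the range of BFUE, also without the Cd34-high cells. Within the range of CFUE lay 7 of them, or 3 without the CFUE cell of well D10. Of 24 cells of the upper intermediate gate, 1 lay within the range of BFUE and 23 within that of CFUE, or 18 without the CFUE cell of well D10.

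**Figure D3:**
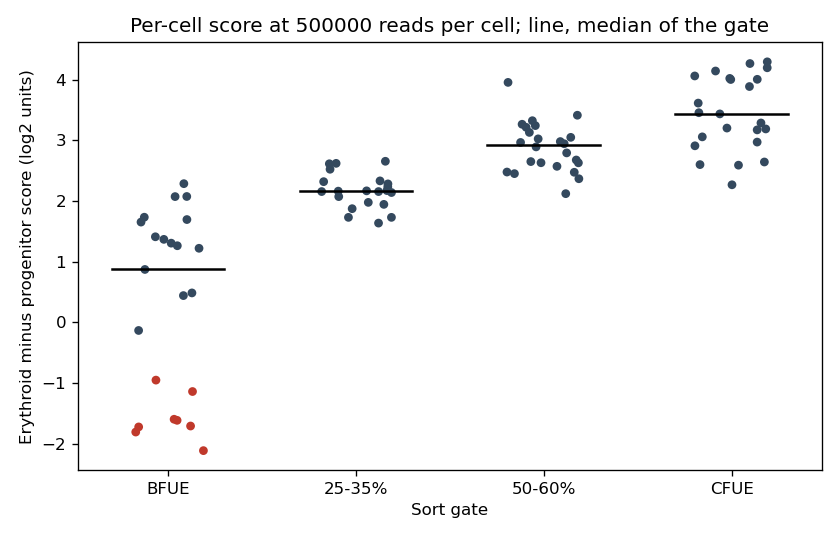
Per-cell score (mean log2 of heme synthesis and membrane genes minus that of stem and multipotent genes) in the 4 sort gates, 1 point per cell, with the gate's median as a line. The 8 Cd34-high BFUE cells, in red, lie between -2.12 and -0.95, below every other cell.

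Shares of cells with a read overstate expression of abundant genes. Cd34 had 1 or more reads in 21 of 23 BFUE cells and in 7 of 23 CFUE cells, and 14 and 4 at 500000 reads per cell. With 10 or more reads these were 8 and 0. For this reason shares of cells with 1 read are not read as expression here. Afp, a gene of the hepatoblast list, had a read in all 23 BFUE cells and in 21 of 23 CFUE cells. These were not all single reads, with 23 in BFUE well A1, 456 in B3 and 950 in A2. A cut at 10 reads would thus leave Afp in such cells, and the source of its reads was not tested. Slc4a1 had a read in 20 of 23 CFUE cells and 10 or more reads in 13.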

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

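All tests of explanations in this part were chosen after the results were seen.

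The 5 wells left out for low depth held reads of the stem and multipotent and the neutrophil and monocyte lists, above the 3 that a count of 0 allows. The counts were 24 in E5, 29 in G5 and 24 in H4 of the lower intermediate gate, 48 in BFUE D2 and 50 in CFUE C12. Reads of the 77 genes abundant in the Cd34-high cells were compared with kept cells of the same plate row. Of the 4 left-out wells outside the BFUE gate, 3 lay within the range of their row, but below its median. They held 24 against a median of 39 in E5, 13 against 35 in H4 and 34 against 42.5 in C12. The exception, G5, held 2 against 7 to 63 in its row. Relative to all reads, the 77 genes stood at 1442, 189, 802 and 2380 CPM in E5, G5, H4 and C12. Kept cells of the later gates in these rows held 27.1, 15.6, 24.3 and 31.1 CPM. The counts were thus higher than in proportion to the total of each well. Reads carried from other wells may account for the counts of these 4 wells, but 4 wells are too few to decide it. BFUE D2 was not compared in this way. Its 12472 reads held 8 of Cd34, 6 of Mpo, 2 of Flt3 and 0 of Gata1. No biological explanation was tested.

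The Cd34-high cells of the BFUE gate touch both comparisons with that gate. A second, erythroid cell in the well would bring Gata1, and the highest Gata1 among the 8 cells was 66.9 CPM against a lowest value of 189 in the other BFUE cells. Sorting errors at one rate over the plate would reach the other gates too, where the share had an upper bound of 5.28% against a lower bound of 16.4% in BFUE. For cells of another type in the gate, the lowest Mpo among the 8 cells, 145 CPM, lay above the highest of all other kept cells, 79.3 CPM, but this was part of the pattern as first seen, and Mpo does not separate another lineage from multipotent progenitors. Whether the gate held progenitors of other lineages that the depletion (CD3e, CD45R, Ly-6G, CD11b, Ter119, Sca-1, CD16/32 and CD41) did not remove stays open.

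Trace reads outside the BFUE gate had a pattern along the plate. The 77 genes made up 28.1 CPM in the 42 cells of plate rows with a Cd34-high cell and 19.7 CPM in the 26 cells of other rows, a ratio of 1.43 (interval 1.31 to 1.55, counting error only). Reads carried between wells of a row could give this difference, but not the larger part of the trace reads, which stood in rows without such a cell too. Rows ranged from 24.3 to 31.1 CPM with such a cell and from 15.6 to 23.8 without, so free RNA shared by all wells cannot be told apart as a source, since the rows of each kind differed by an SD of 3.21 CPM. Only kept cells set this grouping. Row D, at 20.1 CPM, counts as without such a cell, though its left-out well BFUE D2 held Cd34 at 641 CPM, from 8 reads. With row D counted as holding such a cell, the ranges would overlap. No biological explanation was tested.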

How the results depend on the processing

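Leaving out the Cd34-high BFUE cells, the CFUE cell of well D10, the cell with most reads of a gene, or Kit from its list was chosen after the data were seen, and all other alternatives before. No paired analysis was possible because well numbers pair no cells and no test was made. Of the heme synthesis and stem medians, positions, assignment and score, 90 alternative values stayed within the band they were held against and 35 moved. For list medians this band ran between the medians of the members' lower and upper interval bounds, which is no interval of the median itself. The heme synthesis median in CFUE against BFUE (1.68) was 1.79 with TMM factors, 1.28 in rows A to D, 2.04 in rows E to H, 1.84 without the deepest cell of each gate, 1.47 over members at 50 CPM or more and 1.31 without the Cd34-high cells. In the lower intermediate gate against BFUE (0.69) it was 0.76 with TMM factors, 0.75 with DESeq2 factors, 0.49 and 0.76 in rows A to D and E to H, 0.79 without the deepest cells, 0.85 with no filter, 0.83 at 50 CPM or more and 0.31 without the Cd34-high cells. Between the intermediates (0.52) it was 0.45 in rows A to D and 0.56 with no filter, and in CFUE against the upper intermediate gate (0.51) it was 0.20 and 0.68 in rows A to D and E to H. The stem and multipotent median in CFUE against BFUE (-7.25) was -5.85 at 50 CPM or more and -3.52 without the Cd34-high cells. It was -6.65 in rows A to D, -6.25 in rows E to H and -6.38 with thinned counts. These 3 count as unmoved only because its band was wide, at -8.00 to -6.08. In the lower intermediate gate against BFUE (-3.64) the stem median was -4.52 in rows E to H, -4.17 with no filter and -1.50 without the Cd34-high cells. Between the intermediates (-0.30) it was -0.19 and -0.41 in rows A to D and E to H, -0.61 with no filter and -0.10 at 50 CPM or more, and in the last step (-0.44) -0.17 in rows E to H and -0.16 at 50 CPM or more. The positions of the lower intermediate gate were 54.4% with the mean of per-cell CPM (higher genes), and 43.3% (higher) and 46.1% (lower) without the Cd34-high cells. Those of the upper one were 81.6% (higher) and 78.5% (lower) with 4-fold genes, and 75.8% (lower) without the Cd34-high cells. With 4-fold genes its 2 directions lay far apart, at 70.8 and 92.5% (higher) and 71.3 and 85.7% (lower). Each of these kept its sign, and the cause was not tested. The immediate early and heat shock median changed sign, in CFUE against BFUE to 0.029 with no filter, where Jund is counted in place of Egr1 among 9 members, and to 0.28 at 50 CPM or more. In the lower intermediate gate it changed to 0.22 at 50 CPM or more, and only 4 members are counted at that level. Of 1133 alternative values of list medians 65 changed sign, and 62 of these were of medians under 1.5-fold. Of the named genes' ratios 192 values moved, 736 did not and 0 changed direction, but the rule for naming them had required the same direction in both sets of plate rows and in the mean of per-cell CPM. The stricter cell filter removed the same 5 wells, so its values are the main ones. With no cell filter these wells added at most 16644 reads each to the sums, so values could hardly move. Each of the 2 settings gave 8 of the 90 unmoved values and 84 of the 736, which say little about robustness. The score was held against the SD of the BFUE cells, a wide band of 1.53, so its difference of 1.28 with a pseudocount of 100 CPM counts as unmoved from 2.57. Depth limits genes near the floor of 3 counts.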

Other observations

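Within the BFUE gate, cells with Gata1 were not all alike. Among the 15 BFUE cells outside the Cd34-high ones, Gata2 ran from 0.62 to 1353 CPM, the megakaryocyte integrin gene Itga2b from 0 to 881 CPM and Car1 from 3.28 to 4264 CPM. Gata2 had 10 or more reads in 11 of the 15 cells, and in 9 of 21, 2 of 24 and 0 of 23 cells of the later gates in order.

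Globin RNA varied widely within CFUE. Hba-a1 lay between 18.8 and 3076 CPM in the 23 cells, and Slc4a1 had 10 or more reads in 13 of them. The cell of CFUE well D10 stood apart, with 947458 reads in 6361 genes, 1.11% of reads in ribosomal RNA-like genes against a median of 8.84% for the gate, Gata1 at 3.17 CPM and Kit at 5.28 CPM. Without it, a setting chosen after the data were seen, the stem and multipotent progenitor median in CFUE against BFUE was -7.21 against -7.25.

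The growth arrest gene Btg2 differed between sets of plate rows. In CFUE against BFUE its log2 ratio was 0.74 in rows A to D and 4.87 in rows E to H, and 3 of the 8 Cd34-high cells held 10 or more reads of it.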
